A study of Mus musculus with 384 samples.

How the data were processed

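Single T cells sorted from B16F10 melanomas, a transplantable mouse skin tumour line of the C57BL/6 strain, were profiled by Smart-seq2, a plate-based method that reads full-length transcripts of each cell without molecular identifiers. Per the labels' protocols, cells were lysed in plates, their cDNA was amplified by PCR and libraries were made by tagmentation. The deposited table holds 384 wells on 4 plates, and each plate holds 94 single-cell wells, 1 population well and 1 no-cell well. Per the sample titles, the plates hold CD8 cells of source WT4, CD8 cells of source KO4, CD4 cells of WT4 and CD4 cells of KO4. The treatment label speaks of CD8+ cells alone, whereas the titles of 2 plates say CD4, and the plates are grouped here by title. The genotype label gives wild type or Il27ra knockout. WT4 and KO4 were read as 1 source per genotype, each with 1 plate per cell type. This reading is an assumption, since the labels do not explain the 4, the p-number or the animal names in the titles. Under it genotype, animal and plate cannot be separated.

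The values are FPKM (fragments normalized to transcript length and library size) with TMM normalization, as deposited by the authors for 23420 gene symbols. Per the submitters' processing notes, Bowtie and RSEM were used with genome build mm10, and versions are not given in the sources used here. RSEM divides reads that match several genes by an estimate, so values of closely related genes such as Klrc1 and Klrc2 are uncertain. The file holds no read counts. The FPKM that corresponds to 1 read was therefore estimated from the steps between low values, using transcript lengths of GENCODE M21 (GRCm38, the assembly behind mm10), which had a length for 93.0% of the symbols. Of values under 10 estimated reads, 61.3% lay within 0.1 of a whole number, against 20% if they were spread evenly. This share is too low to treat the values as counts, so the estimated reads per cell served only to describe and match depth. On 200 simulated wells and 12246 genes, the log of the fitted step correlated with minus the log of the true depth at r = 0.965. This checks relative depth and not absolute read numbers. Over the kept cells, 1 read in a gene of 2 kb was worth a median of 0.95 FPKM (range 0.36 to 3.01).

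A gene was called detected at 1 FPKM or more, and cells with at least 1000 detected genes were kept, which left 301 of 376 cells. Per gene, the mean over kept cells of log2(FPKM + 1) was computed for each plate and the wild-type mean was subtracted from that of the plate labelled knockout. Differences on this scale understate changes of genes with low values. They also carry the share of cells with detection, so they are not fold changes of mean expression and can be wider or narrower. For CD4 minus CD8, Ccl5 differed by -7.02 log2 on this scale and -3.53 with arithmetic means, whereas Foxp3 differed by 3.81 and 7.11. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only and not the spread between animals. Cells of 1 source are not replicates, so no p-value, standard error or count of changed genes was computed for genotype. For each of 24 gene lists, the median difference was taken over members detected in at least 10% of kept cells of either plate (8117 genes passed in CD8 and 7063 in CD4). Its percentile was read among 10000 random lists of the same size drawn from the other genes and matched on decile of mean level. A list of at least 3 measured genes was said to stand apart below percentile 2.5 or above 97.5. This describes the libraries and does not test genotype. Of 200 simulated lists of 13 genes for the CD8 comparison of 8117 genes, 5.5% stood apart with no shift, 86% with a shift of 0.5 log2 and 100% with a shift of 1 log2. The simulated lists were genes picked at random with shuffled differences, whereas genes of a real list can move together. The 5.5% therefore does not give how often a real list stands apart without a genotype effect. Of the list members, 5 were found under an older symbol and 3 were not matched to a symbol.

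CD4 and CD8 plates were compared with limma (version 3.58.1, R 4.3.3; lmFit and eBayes with trend) on the 4 plate means, with the genotype source as a block and Benjamini-Hochberg adjustment over 8427 genes, and adjusted p under 0.05 was the threshold. The fit has 1 residual degree of freedom, and the spread it uses comes from all genes together, with an infinite estimated prior weight. The residual degree of freedom holds the part by which the CD4 to CD8 difference itself differs between the 2 sources. The labels do not say that the plates come from separate mice beyond the source name. These p-values therefore rest on a spread between 4 plates pooled over all genes. They measure neither each gene's own spread nor the spread between mice. On simulated values of the same 8427 genes for CD4 against CD8, 48% of 50 genes changed by 1 log2 were recovered, 90% of 50 changed by 2 log2 and 100% of 50 each changed by 4 and by 6 log2, with 15 unchanged genes called. The simulated noise was drawn from the fit's own pooled spread, and both cell types were given the same genotype difference. The simulation therefore does not give recovery or false calls where genes depart from that model. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Gene positions are those of GENCODE M21.

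The groups, lists, rule for named genes, tests and most alternatives were fixed before the data were examined. Named genes were Il27ra, every measured member of the co-inhibitory and IL-27-linked surface lists, up to 4 members of each other list with the widest genotype difference, and for each cell type the 8 genes each way with the widest difference among genes detected in at least 25% of cells of a plate. Also named were the 6 genes each way with the widest difference shared by CD4 and CD8, and the 6 genes each way with the smallest p between CD4 and CD8. Gene models, ribosomal protein genes, receptor segments and sex-linked markers were not named by rank. The alternatives changed the cell filter, doubtful cells, scaling, pseudocount, averaging, matching of cells on detected genes, gene filter, population libraries in place of cells, Foxp3-positive cells, the block and trend of limma and the plates in the fit. Matching on estimated reads and centring of plates were added after the data were seen. Doubtful cells lack Cd3d, Cd3e and Cd3g or hold at least 3 markers of the melanoma, myeloid and B cell lists, of which Tyr, detected in nearly every cell, supplied 1 in most cells. T cell receptor segments were planned but are not analysed here, since 0 symbols of the table start with Trbv or Trav. The chance of other splits of the samples was not computed, since no comparison has 3 samples per group.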

Results

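Expression was measured in tumour-infiltrating CD8 and CD4 T cells from a wild-type and an Il27ra knockout source, to describe the genes linked to IL-27, a cytokine of the IL-12 family, in the tumour. After the cell filter, 72 of 94 CD8 cells of the wild-type source and 77 of 94 of the source labelled knockout were kept, as were 74 of 94 and 78 of 94 CD4 cells. The wild-type CD8 plate was the deepest, with a median of 2530 detected genes and an estimated 923409 reads per kept cell. The CD8 plate labelled knockout had 2243 genes and 659151 reads, the wild-type CD4 plate 2047 genes and 686464 reads and the CD4 plate labelled knockout 2091 genes and 680572 reads. The 4 population libraries held between 9918 and 10848 detected genes. The no-cell wells held 11, 8, 26 and 6 detected genes in the same order of plates.

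Lineage markers matched the titles. Cd4 (chromosome 6, 124864692 to 124888221) was detected in 89.2% of wild-type CD4 cells and 91% of CD4 cells labelled knockout. It was detected in 0 of 72 wild-type CD8 cells (95% interval 0.0 to 5.0) and in 1 of 77 CD8 cells labelled knockout (0.0 to 7.0), intervals that limit the share of cells with detected RNA and not the share expressing the gene. Cd8a (chromosome 6, 71373427 to 71379173) was detected in 84.7% and 81.8% of CD8 cells and in 2.7% and 0.0% of CD4 cells. RNA of other cell types was uneven over the plates. Dct, an enzyme of pigment synthesis, was detected in 15.3% of wild-type CD8 cells (95% interval 7.9 to 25.7) and 1.3% of those labelled knockout (0.0 to 7.0), and in 13.5% and 0.0% of the CD4 cells. Not every marker leaned that way by share of cells. Lyz2, a myeloid marker, was detected in 5.4% of wild-type CD4 cells (1.5 to 13.3) and 15.4% of those labelled knockout (8.2 to 25.3). By mean FPKM it leaned to wild type, at 652.69 against 346.06. The myeloid marker Fcer1g was detected in 15.3% and 13% of the CD8 cells. Doubtful cells made up 31.9% and 16.9% of the CD8 plates and 23% and 9.0% of the CD4 plates, wild type first.

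Il27ra, which encodes the specific chain of the IL-27 receptor and was the targeted gene (chromosome 8, 84030294 to 84042589, minus strand), did not separate the single cells by label. It was detected in 51.4% of wild-type CD8 cells (39.3 to 63.3) and 57.1% of CD8 cells labelled knockout (45.4 to 68.4), and in 36.5% (25.6 to 48.5) and 47.4% (36 to 59.1) of CD4 cells. The difference of means was 0.28 log2 in CD8 and 0.16 log2 in CD4, labelled knockout minus wild type. Mean FPKM went the other way, from 101.5 in wild type to 74.8 in CD8 and from 103.2 to 64.1 in CD4. The population libraries also had lower values under the knockout label, 92.9 against 155.4 FPKM in CD8 and 133.4 against 244.6 FPKM in CD4. The values are per gene, and the part deleted in these mice is not given in the sources used here, so transcripts outside the deletion can count and these values do not check the labels. All genotype differences below are therefore differences between plates as labelled.

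In CD8 cells, genes of co-inhibitory receptors were lower in the plate labelled knockout, and genes of naive and memory T cells were higher. Pdcd1 (chromosome 1, 94038305 to 94052553), which encodes PD-1, was detected in 62.5% of wild-type cells (50.3 to 73.6) and 32.5% of cells labelled knockout (22.2 to 44.1), with mean log2 values of 6.45 ± 5.11 (SD over 72 cells) and 2.82 ± 4.37 (SD over 77 cells). Havcr2, which encodes TIM-3 (chromosome 11, 46454935 to 46481255), was detected in 45.8% (34 to 58) and 11.7% (5.5 to 21.0). Lag3 (chromosome 6, 124904361 to 124911705) was detected in 63.9% (51.7 to 74.9) and 24.7% (15.6 to 35.8). Tigit (chromosome 16, 43648867 to 43664146) was detected in 80.6% (69.5 to 88.9) and 58.4% (46.6 to 69.6).

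Of 13 measured co-inhibitory receptor genes, 10 lay below the median of all genes, which was -0.22 log2, and the list median was -1.27 (percentile 0.0 of the random lists). Besides Pdcd1 (-3.63), Lag3 (-3.35), Havcr2 (-2.75) and Tigit (-2.24), the ectonucleotidase gene Entpd1 differed by -2.54 and Cd244 by -1.27. Nt5e, which encodes the ectonucleotidase CD73, differed by 1.18 in the opposite direction, as did Cd96 by 0.83. In the population libraries the list median was -0.40, at percentile 3.22 and so no longer apart, and Lag3 was at 1029 against 1103 FPKM. The list of IL-27-linked surface and cytokine genes, which shares Pdcd1, Havcr2, Lag3 and Tigit with the former, had a median of -0.71 and stayed within the random lists (percentile 4.56). Among its other members Il10ra differed by -2.44, whereas Cd274, which encodes PD-L1, differed by 0.67 and Il12rb2 by 0.63. Its median was 0.01 in the population libraries and -0.14 with arithmetic means, but it stood apart without doubtful cells (-1.06, percentile 0.29), with the 25% gene filter (-2.24, percentile 0.0) and in cells matched on detected genes (-0.75, percentile 0.03).

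**Figure D1:**
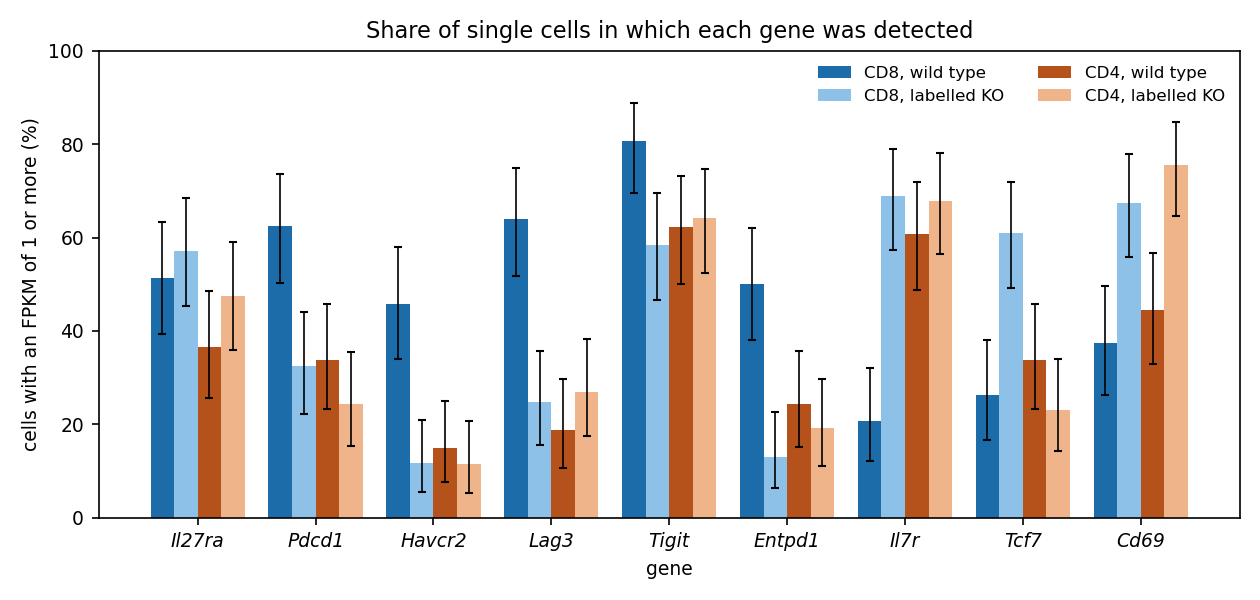
Share of kept single cells with an FPKM of 1 or more (vertical axis, percent) for 9 genes (horizontal axis) on each of the 4 plates, with bars for shares and whiskers for exact 95% intervals of counting error only. Pdcd1, Havcr2, Lag3, Tigit and Entpd1 were detected in a larger share of wild-type CD8 cells than on the other plates, and Il7r and Tcf7 in 20.8% and 26.4% of wild-type CD8 cells against 68.8% and 61% of those labelled knockout.

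Of 13 naive and memory genes, 12 lay above the median of all genes in the CD8 plate labelled knockout, and the list median was 1.44 (percentile 100) in cells and 1.59 in the population libraries. Il7r, the survival cytokine receptor of naive and memory cells (chromosome 15, 9505788 to 9530176), differed by 4.04, the transcription factor gene Tcf7 (chromosome 11, 52252371 to 52283014) by 2.89, the lymph node homing receptor gene Ccr7 by 2.74 and Slamf6 by 2.00. All 24 proliferation genes were lower in the plate labelled knockout (median -1.12, percentile 0.0, population -0.84), with differences of -2.37 for Stmn1, -2.31 for Hmgb2 and -2.05 for Rrm1. In cells matched on estimated reads, a setting chosen after seeing the data, the median was -0.21 (percentile 10.97), so this list did not stand apart in the 35 cells per plate matched that way. Of 17 glycolysis genes 15 were lower (median -0.75, percentile 0.79), with -2.17 for Pgk1 and -1.84 for Tpi1, and the median was -0.02 in the read-matched cells.

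The list of immediate early and heat shock genes had a median of 1.04 in the CD8 plate labelled knockout (14 of 17 above the median of all genes, percentile 100, population 1.40). Of its 13 immediate early members 12 lay above the median of all genes (median 1.63, percentile 100), whereas its 4 heat shock members stayed within the random lists (median -0.26, percentile 60.03). Examples are Ier2 (3.48), Junb (3.36), Fosl2 (2.26) and Fos (2.07). Interferon-stimulated genes had a median of 0.31 (17 of 22 above, percentile 100), with 1.69 for Irf7 and 1.28 for Ifit3 but -1.62 for Zbp1. With only genes detected in at least 25% of cells, their median was -0.09 (percentile 87.55). The receptors of IL-27 and related cytokines had a median of 0.34 (8 of 14 above, percentile 99.87), with Il2rg at 1.78 and Il18r1 at 1.52. Without doubtful cells it was 0.09 (percentile 95.31). Tissue-residence genes had a median of 0.32 (percentile 99.41), with Cd69 at 3.51 but Cxcr6 at -1.65, and the median turned to -0.53 in cells with at least 2000 detected genes.

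The other CD8 lists stayed within the random lists. These were the IL-27-linked transcription factors (median -0.11), cytotoxic effector genes (-0.40), cytokines and chemokines (-0.14), co-stimulatory receptors (-0.14), dysfunction-linked transcription factors (0.09), regulatory T cell genes (-0.11), T cell identity (-0.33), CD8 lineage (-0.84), CD4 lineage (0.29), melanoma markers (-0.69, 3 genes) and housekeeping genes (0.08). Single members differed widely within them. The transcription factor gene Tox, linked to exhausted T cells, differed by -2.75 and Prdm1 by -1.27, while Socs1 differed by 2.30 and Socs3 by 1.99. The granzyme gene Gzmk was detected in 50% of wild-type cells (38 to 62) and 9.1% of cells labelled knockout (3.7 to 17.8), and Gzmb in 55.6% and 33.8%. Of the myeloid, B cell, NK cell and stromal lists, 1 gene each was measured, and Fcer1g differed by -0.31, Cd22 by 0.20, Gzma by 0.39 and Pecam1 by 0.35.

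Ranked over all genes, the widest lower differences in the CD8 plate labelled knockout were those of Gzmk (-3.91), Pdcd1, Anxa2 (-3.60), Gimap7 (-3.56), Lag3, Tox, Havcr2 and Dctn2 (-2.68). Dctn2 was higher in the population library labelled knockout, at 304.7 against 269.6 FPKM. The widest higher differences were those of Il7r, Ppp1r15a (3.72), Cd69, Emb (3.50), Ier2, Junb, Nfkbiz (3.0) and Tcf7. Emb, an adhesion protein gene, was detected in 44.4% of wild-type cells (32.7 to 56.6) and 84.4% of cells labelled knockout (74.4 to 91.7). Each of these rests on 1 plate per genotype with no replicate check.

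**Figure D2:**
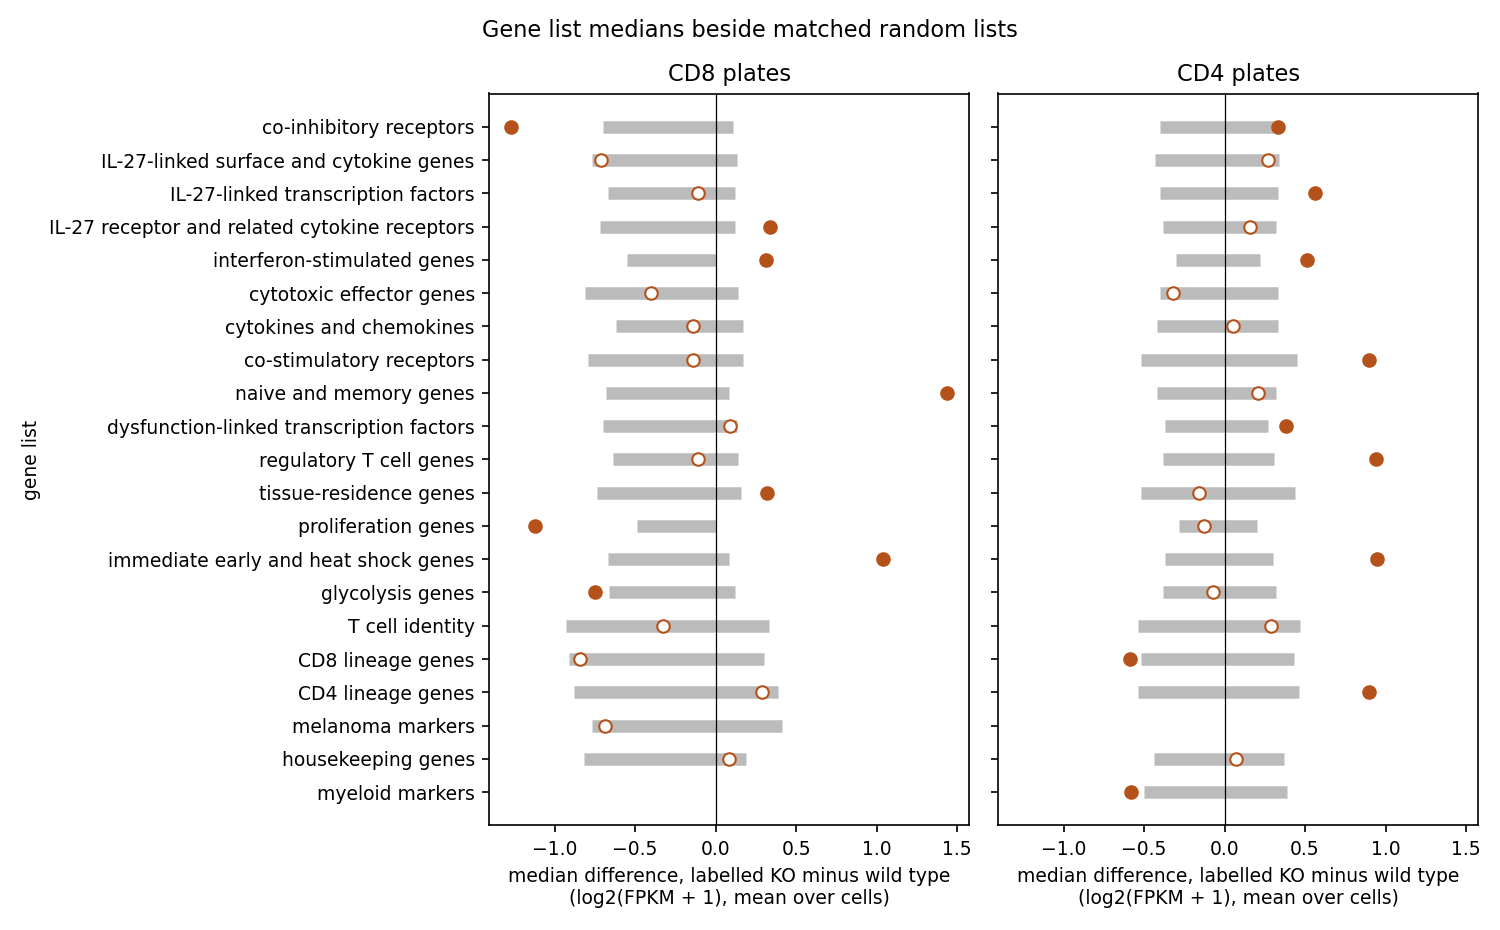
Median difference, labelled knockout minus wild type, of mean log2(FPKM + 1) over cells (horizontal axis) for each gene list (vertical axis) in CD8 and CD4 plates, with circles for list medians, filled where they stand apart, and grey bars that span the central 95% of 10000 matched random lists. Co-inhibitory receptors lie at -1.27 in CD8 and 0.33 in CD4, and immediate early and heat shock genes at 1.04 and 0.95.

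The number of receptors detected per cell was compared between plates and with independent detection at each plate's own rates, which takes no account of differences in depth between cells. At least 3 of Pdcd1, Havcr2, Lag3 and Tigit were detected in 56.9% of wild-type CD8 cells (44.7 to 68.6) and 19.5% of those labelled knockout (11.3 to 30.1). In CD4 cells the shares were 14.9% (7.7 to 25.0) and 12.8% (6.3 to 22.3), whose intervals overlap. Independent detection gives 52.9% and 7.9% in CD8 and 8.0% and 7.3% in CD4, so the share in wild-type CD8 cells lay close to it. All 4 were detected in 43.1% of wild-type CD8 cells, where independent detection gives 14.7%, and in 10.4% of those labelled knockout, where it gives 0.5%. In CD4 cells the shares were 8.1% against 0.6% and 3.8% against 0.5%. Cells with none of the 4 were also more frequent than under independent detection, at 11.1% against 1.4% and 29.9% against 18.7% in CD8 and 27% against 17.3% and 25.6% against 17.6% in CD4. Lag3 and Havcr2 were both detected in 45.8% of wild-type CD8 cells (34 to 58, 29.3% if independent) and 11.7% of those labelled knockout (5.5 to 21.0, 2.9% if independent). In cells matched on the number of detected genes, the share with at least 3 was 46.8% in wild-type CD8 cells and 19.1% in those labelled knockout.

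**Figure D3:**
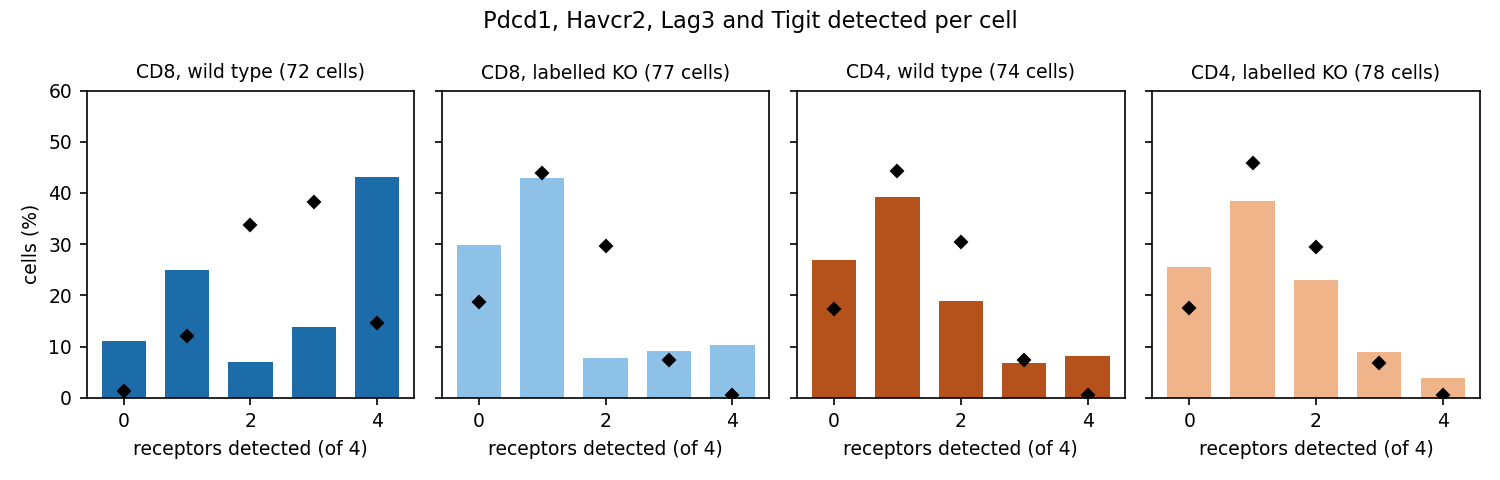
Number of the 4 genes Pdcd1, Havcr2, Lag3 and Tigit detected per cell (horizontal axis) and share of kept cells (vertical axis, percent) on each plate, with bars for observed shares and diamonds for the shares given by independent detection at the plate's rates. All 4 were detected in 43.1% of wild-type CD8 cells.

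In CD4 cells the co-inhibitory list stood apart on the higher side in the plate labelled knockout, but not in the population libraries. Genes of regulatory T cells, of co-stimulation and of the immediate early response were also higher in that plate. Among these, only the immediate early and heat shock list also stood apart in the population libraries. Foxp3, the lineage factor of regulatory T cells (chromosome X, 7573644 to 7595245), was detected in 36.5% of wild-type cells (25.6 to 48.5) and 47.4% of cells labelled knockout (36 to 59.1), intervals that overlap, and its population values were 967 and 961 FPKM. Il2ra, the high-affinity IL-2 receptor chain, was detected in 27% (17.4 to 38.6) and 53.8% (42.2 to 65.2), and Fos in 40.5% (29.3 to 52.6) and 79.5% (68.8 to 87.8).

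The median of all genes in CD4 was -0.04 log2. Of 12 co-inhibitory genes 9 lay above it, with a list median of 0.33 (percentile 98.14), but the population median was 0.05 (percentile 34.63) and the median with arithmetic means 0.00. Pdcd1 differed by -0.68 (0.44 without Foxp3-positive cells), Havcr2 by -0.20, Lag3 by 0.49, Tigit by 0.35, Nt5e by 0.77 and 4632428N05Rik, the older symbol of Vsir, by 1.07. The latter pair reversed in the population libraries (-0.08 and -0.10). The IL-27-linked surface and cytokine genes had a median of 0.27 (percentile 94.68, within the random lists), with Ly6a at 1.71, Cd274 at 1.57 and Il10 at 0.20. Without Foxp3-positive cells their median was 0.69 (percentile 99.29), and in cells with at least 2000 genes it was -0.42 (percentile 6.96).

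Of 14 regulatory T cell genes 13 lay above the median of all genes (median 0.94, percentile 100), with 2.12 for Capg, 1.55 for Il2ra, 1.41 for Tnfrsf9 and 1.35 for Tnfrsf4. The population median was 0.17 (percentile 60.63). Co-stimulatory receptors had a median of 0.90 (8 of 10 above, percentile 99.99), with 1.28 for Icos and 1.00 for Tnfrsf18 (-0.30 in the population libraries). CD4 lineage genes also had a median of 0.90 (6 of 8 above, percentile 99.94). They share Icos, Tnfrsf4, Il2ra, Foxp3, Cd40lg and Ctla4 with the co-stimulatory and regulatory T cell lists, so this is largely the same result. The population medians of the co-stimulatory and CD4 lineage lists were -0.02 and 0.19, within the random lists. Without Foxp3-positive cells the co-stimulatory median was 0.37 (percentile 87.88). Immediate early and heat shock genes had a median of 0.95 (12 of 17 above, percentile 100) in cells and 0.99 in the population libraries. The median was 1.46 over the 12 immediate early members (percentile 100) and -0.20 over the 5 heat shock members (percentile 27.78), with 4.16 for Fos, 3.05 for Egr1, 2.52 for Ier2 and 2.48 for Fosb.

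The IL-27-linked transcription factors had a median of 0.56 (10 of 14 above, percentile 99.93), with 1.62 for Irf4, 1.59 for Socs1 and 1.46 for Irf1 but -1.27 for Id2. The difference of Id2 turned to 0.52 in the population libraries and to 0.53 without Foxp3-positive cells. The population median of the list was 0.27 (percentile 86.98). Interferon-stimulated genes had a median of 0.51 (17 of 20 above, percentile 99.99), with 1.36 for Gbp3 and 1.23 for Igtp, and a population median of 0.23 (percentile 80.75). Dysfunction-linked transcription factors had a median of 0.38 (7 of 10 above, percentile 99.56) and a population median of 1.13, with 2.15 for Nr4a1 and 1.32 for Egr2 but -1.57 for Nfatc1, which turned to 0.97 in the population libraries. CD8 lineage genes were lower (median -0.59, percentile 1.26), with -1.90 for Nkg7 and -1.68 for Ccl5, and their population median was 0.26. Of 3 measured myeloid markers, Fcer1g differed by -0.90, Apoe by -0.58 and Lyz2 by 0.06 (median -0.58, percentile 0.72), with a population median of 3.79.

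The other CD4 lists stayed within the random lists. These were the IL-27 receptor and related cytokine receptors (median 0.16), cytotoxic effector genes (-0.32), cytokines and chemokines (0.05), naive and memory genes (0.21), tissue-residence genes (-0.16), proliferation genes (-0.13), glycolysis genes (-0.07), T cell identity (0.29) and housekeeping genes (0.07). Fewer than 3 melanoma, B cell and stromal markers were measured, where Dct differed by -0.64, Tyr by 0.11, Cd22 by -0.33 and Pecam1 by 0.07, and 0 NK cell markers. The widest lower differences in the CD4 plate labelled knockout were those of Tspan13 (-2.48), Eif3f (-2.32), Sdha (-2.13), Hnrnpr (-1.99), Nkg7, Cox7a2l (-1.85), Pstpip1 (-1.82) and Sash3 (-1.80). Of these Nkg7, Cox7a2l and Pstpip1 were higher in the population library labelled knockout. The widest higher differences were those of Fos, Cd69 (3.35), Ppp1r15a (3.32), Cish (3.16), Egr1, Serinc3 (2.73), Nfkbiz (2.60) and Zfp868 (2.55). Cish, a feedback inhibitor of cytokine signalling, was detected in 36.5% of wild-type cells and 66.7% of cells labelled knockout.

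Several genes differed the same way in both cell types. The activation marker gene Cd69 (chromosome 6, 129267325 to 129275436) was detected in 37.5% of wild-type CD8 cells and 67.5% of those labelled knockout, and in 44.6% and 75.6% of the CD4 cells. Ppp1r15a, a stress-response phosphatase subunit gene, differed by 3.72 in CD8 and 3.32 in CD4, Nfkbiz by 3.0 and 2.60, Zfp868 by 2.74 and 2.55, Ier2 by 3.48 and 2.52 and H60b by 2.42 and 2.28. All 6 were also higher in both population libraries labelled knockout. For H60b, which encodes a ligand of the receptor NKG2D, the population values were 12.01 and 120.9 FPKM in CD8 and 18.7 and 146.5 FPKM in CD4, wild type first. The widest shared lower differences were those of the chemokine gene Ccl5 (-1.75 in CD8 and -1.68 in CD4), Sash3 (-1.64 and -1.80), Nudt21 (-1.60 and -1.74), Pstpip1 (-1.43 and -1.82), Cenpa (-1.39 and -1.43) and Lars2 (-1.38 and -1.42). Of these, Ccl5, Nudt21 and Pstpip1 were higher in the CD4 population library labelled knockout, and the CD8 difference of Cenpa turned to 0.28 in cells matched on estimated reads.

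CD4 and CD8 plates differed in lineage genes as titled. All 8 CD8 lineage genes were lower in CD4, and 7 of 8 CD4 lineage genes were higher (8 and 8 adjusted over the list alone). Cd4 differed by 7.42 log2 (SE 0.53, limma adjusted p = 1.92e-40), Cd8a by -7.38 (SE 0.53, limma adjusted p = 2.94e-40) and Foxp3 by 3.81 (SE 0.41, limma adjusted p = 1.45e-17), each with the same sign in both sources. The other genes with the smallest p were Cd40lg (2.34), Icos (3.67), Tnfrsf4 (3.51) and the gut-homing integrin gene Itgb7 (3.94), which were higher in CD4, and Ccl5 (-7.02), Cd8b1 (-7.36), Nkg7 (-6.50), Klrd1 (-4.45) and Klrc1 (-4.05), which were lower. In cells with at least 2000 detected genes, Cd40lg, Icos, Tnfrsf4 and Itgb7 did not pass (limma adjusted p from 0.0694 to 0.136). The lower genes named here still passed in that setting. Of 14 regulatory T cell genes 8 were higher in CD4 and none lower (13 and 0 adjusted over the list alone). Of 13 cytotoxic effector genes 6 were lower (10 adjusted over the list alone), among them Gzmk, Prf1 and Ctsw. Of 24 proliferation genes 9 were lower in CD4 (18 adjusted over the list alone), and of 18 immediate early and heat shock genes 6 were higher (7 adjusted over the list alone). The proliferation list also differed between the CD8 plates, with a median of -1.12, labelled knockout minus wild type. Between the CD4 plates the median was -0.13 over 16 measured members, so the gap between CD4 and CD8 depends on the source. List counts were not recomputed with plates centred, where 23 of all genes were lower in CD4 against 533 without. Of 22 interferon-stimulated genes limma called 0, also adjusted over the list alone (4 at unadjusted p under 0.05).

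Of 14 co-inhibitory genes, 6 were lower in CD4 and Klrg1 was higher (6 and 3 adjusted over the list alone). The difference of Pdcd1 was -2.48 (SE 0.51, limma adjusted p = 1.76e-04), but it was -3.95 in the wild-type plates and -1.01 in the plates labelled knockout. Without the genotype block and with all 4 plates, limma adjusted p was 0.143 for Pdcd1 and 0.274 for Havcr2. In a fit without the block and without the wild-type CD8 plate, the difference of Pdcd1 was -0.67 (limma adjusted p = 0.559), and Havcr2 turned from -1.27 to 0.10. Over 17 alternatives the adjusted p ranged from 1.82e-04 to 0.559 for Pdcd1 and from 0.00271 to 0.940 for Havcr2. Il27ra differed by -0.80, which did not pass (limma adjusted p = 0.344).

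Over all genes, 94 were higher and 533 lower in CD4, while the median of all tested genes was -0.27 log2. With plates centred on their median gene, an alternative added after the data were seen, 48 were higher and 23 lower, so the share of calls that were higher in CD4 was 15% without and 67.6% with centring. As shares of the 8427 genes tested, these were 1.12% higher and 6.32% lower as reported. With the population libraries limma called 0 genes (1066 at unadjusted p under 0.05). Without the genotype block and with all 4 plates, 0.237% of the tested genes were higher and 0.593% lower. Fits that leave out a plate also have no block, since with it no residual degree of freedom is left. Without the CD4 plate labelled knockout 0.119% of the tested genes were higher and 0.202% lower, without the wild-type CD4 plate 0.463% and 0.320%, without the wild-type CD8 plate 0.237% and 1.45%, and without the CD8 plate labelled knockout 0.914% and 12.7%.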

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

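The tests of explanations in this part were chosen after the results were seen, although the settings without doubtful cells and with population libraries had been planned. The co-inhibitory receptor list drew attention because its median stood apart in opposite directions, at -1.27 in CD8 and 0.33 in CD4, labelled knockout minus wild type. The difference between the cell types was not tested, since each direction comes from 1 plate per genotype. The CD4 value did not hold in the population libraries (0.05) or with arithmetic means (0.00).

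For the lower co-inhibitory receptors of the CD8 plate labelled knockout, the lower number of reads per cell in that plate does not account for the whole difference, since the median was -0.76 in 35 cells per plate matched on estimated reads (percentile 0.03), although part of it may. The cells flagged as doubtful for RNA of melanoma, myeloid or B cells do not account for it either, since the median was -1.55 without them (percentile 0.0). Cells with fewer than 3 such markers stay in that setting, so it cannot exclude smaller amounts of such RNA. Which single cells happened to be sorted stays open: the population median was -0.40, at percentile 3.22 of its random lists, with 1 library per plate. Animal, plate and genotype cannot be told apart by this design, and genotype stays an untested explanation.

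The no-cell wells held signal that enters no comparison. Genes detected there numbered 11 in the wild-type CD8 plate, 8 in the CD8 plate labelled knockout, 26 in the wild-type CD4 plate and 6 in the CD4 plate labelled knockout. In the well of 26 genes, Anxa2 stood at 3023 FPKM and Il2rg at 1288 FPKM, and Cd4 and Cd8a were not among the genes detected.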

How the results depend on the processing

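Matching on estimated reads and centring of plates were chosen after seeing the data. Of 490 values of 40 list medians under alternatives, 61.8% moved by less than the spread of the random lists, 36.9% moved further and 6 reversed. Of 2183 values of named genes, 77.6%, 20% and 51 did so. Of the 8 CD8 lists that stood apart, 2 did so under every setting (naive and memory genes, immediate early and heat shock genes), as did 2 of 10 CD4 lists (immediate early and heat shock genes, and myeloid markers wherever 3 were measured, with a reversed sign in populations). The cause was not tested unless stated.

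The CD8 co-inhibitory median (-1.27) was -0.95 without cell filter, -1.51 with at least 2000 genes, -1.55 without doubtful cells, -1.90 and -0.68 with pseudocounts 0.1 and 10, -0.87 and -0.76 in cells matched on genes and on reads, -1.02 and -1.87 with no gene filter and one of 25%, and -0.40 in populations. The CD4 value (0.33) was 0.06 with 2000 genes, 0.00 with arithmetic means and 0.05 in populations, within its random lists and below their median of 0.11. The CD8 IL-27-linked surface median (-0.71) was -0.28, -1.06, -0.45, -0.14, -0.35, -2.24, 0.01 and -0.41 with no cell filter, no doubtful cells, pseudocount 10, arithmetic means, no gene filter, a 25% filter, populations and matched reads. In CD4 (0.27) it was -0.42 with 2000 genes, -0.22 with arithmetic means and 0.69 without Foxp3 cells. The share with at least 3 receptors was 43.6% in wild-type CD8 cells without filter (56.9% with it) and 26.8% in wild-type CD4 cells with 2000 genes (14.9%).

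The share of tested genes called between CD4 and CD8 (1.12% higher, 6.32% lower in CD4) was 0.0221% and 0.0996% with 2000 genes, 0.692% and 2.75% with the 25% filter (fewer genes tested), 0% and 0% in populations, 0.0831% and 0.142% with pseudocount 10, 0.658% and 2.07% without doubtful cells, 0.570% and 0.273% with centred plates, 0.237% and 0.593% without block and 0.356% and 1.78% without trend. With arithmetic means 1.07% were lower. Leaving out a plate together with the block, with which no residual degree of freedom is left, gave 0.119% to 0.914% higher and 0.202% to 12.7% lower, to be read beside the values without block. A lone plate is there assumed to vary like the others. Of the values of 17 single genes, 17% lost the threshold, and Havcr2 (-1.27) ranged from -2.65 without the CD8 plate labelled knockout to 0.10, reversed, without the wild-type CD8 plate, both without block.

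Reversed in populations were, in CD8, Ccl4 (0.19), Cd200r1 (0.42), Dctn2 (0.18), Ikzf2 (-1.0), Irf8 (0.06), Isg15 (-0.90), Rbpj (1.00) and Runx3 (0.40). In CD4 they were the medians of co-stimulatory receptors (-0.02), CD8 lineage genes (0.26) and myeloid markers (3.79), and 4632428N05Rik (-0.10), Apoe (4.93), Ccl4 (2.11), Ccl5 (0.10), Cd22 (0.65), Cd3d (0.03), Cd8b1 (4.28), Cox7a2l (0.29), Fcer1g (3.14), Foxp3 (-0.01), Hmgb2 (0.22), Id2 (0.52), Il18r1 (0.97), Nfatc1 (0.97), Nkg7 (0.26), Nt5e (-0.08), Nudt21 (0.38), Pgk1 (0.05), Pstpip1 (1.29), Rbpj (0.48), Rgs1 (0.14), Rplp0 (0.32), Serpinb9 (1.28), Tk1 (0.82) and Tnfrsf18 (-0.30). Matched reads reversed, in CD8, glycolysis genes (-0.02, against the random lists), Ccl3 (0.09), Cenpa (0.28), Irf8 (0.04), Rbpj (0.01) and Tnfrsf9 (0.63), and matched genes Pgam1 (0.59). With 2000 genes, CD8 tissue-residence genes (-0.53) and in CD4 Hmgb2 (0.57) and Klrd1 (-0.03) reversed. Without Foxp3 cells Foxp3 (-0.01, by construction), Gzmb (-0.22), Id2 (0.53) and Pdcd1 (0.44) did. Without doubtful cells Ikzf2 (-0.10) and Pmel (0.17) in CD8 and Apoe (0.06) in CD4 did, and with arithmetic means Ccl4 (0.89) and Nt5e (-0.41) in CD4. Genes worth less than 1 read in 2 kb, 0.95 FPKM at the median, are beyond this depth.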

Other observations

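The tests of explanations in this part and the setting matched on estimated reads were chosen after the results were seen, whereas the population libraries and the setting without Foxp3-positive cells had been planned. Chemokine genes did not move together between the CD8 plates. Ccl3, Ccl4 and Ccl5 differed by -1.80, -1.56 and -1.75, labelled knockout minus wild type, and Xcl1, which attracts cross-presenting dendritic cells, by 0.77. In the population libraries, Xcl1 stood at 1288 against 260 FPKM and Ccl3 at 949 against 3736 FPKM, but Ccl4 at 3774 against 3311 FPKM. In cells matched on estimated reads, the difference of Ccl3 was 0.09, so its lower value did not hold there. In CD4 cells, Gzmb stood at 1815 against 1174 FPKM on average and at 4227 against 1207 FPKM in the population libraries, a direction opposite to CD8, where the populations held 1084 against 4227 FPKM. Without Foxp3-positive cells the CD4 difference of Gzmb was -0.22, the same sign as in CD8, so the opposite direction did not hold there. Tyr, a melanoma marker, was detected in 100% of wild-type CD8 cells and 97.4% of those labelled knockout, at a mean of 20.4 and 8.94 FPKM. In CD4 cells it was detected in 100% and 98.7%. The other melanoma markers were detected in at most 15.3% of kept cells of a plate (Dct, wild-type CD8). They did not share the detection of Tyr in nearly every cell, so Tyr alone does not mark melanoma RNA in a cell. Tyr stood at 0.0 FPKM in all 4 no-cell wells. The lowest value detected in those wells was 86.2 FPKM, so they cannot show background at the level of Tyr. Lars2 stood at 2462 FPKM in the no-cell well of the CD8 plate labelled knockout.

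The immediate early and heat shock list stood higher in both plates labelled knockout. The number of reads does not account for it, since the list medians were 0.97 in CD8 and 1.48 in CD4 in cells matched on estimated reads (percentile 100 for both). Nor do the members within 20 Mb of Il27ra, since without them the medians were 1.04 and 1.05. The heat shock members did not share the shift, with medians of -0.26 in CD8 (percentile 60.03) and -0.20 in CD4 (percentile 27.78). Handling of the plates before lysis may still differ between the sources and cannot be told apart from genotype, since each source has its own plates.

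Genes near Il27ra on chromosome 8 differed alike in CD8 and CD4. Across genes within 20 Mb that were detected in at least 25% of cells of a plate, not counting Il27ra, the differences of the 2 cell types correlated at r = 0.59, where the median of equally wide windows elsewhere in the genome was 0.10 and the highest 0.57. Genes are not independent replicates. The immediate early genes there, such as Junb (84974484 to 84978718) and Ier2 (84661331 to 84662852), do not account for all of it, since r was 0.54 over 97 genes without that list (percentile 99.70 of the windows, highest elsewhere 0.57) and 0.46 without Zfp868 as well (percentile 97.92). Nor do the genes already ranked for a shared difference, such as Zfp868 and Nudt21, account for all of it. Without these and that list r was 0.43 over 95 genes (percentile 99.70, highest elsewhere 0.47), against 0.54 without the list alone, so the ranked genes carry part of it. Genes left out near Il27ra or by rank were also left out of the windows elsewhere, so the percentiles have different references. The windows overlap, so these percentiles are not independent tests. DNA of another strain carried along with the targeted gene is a candidate explanation that stays open. Over the 97 genes without the immediate early list, r was 0.54 in single cells but -0.11 in the population libraries (percentile 40.95), where each plate has 1 library.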
